A study of Mus musculus with 18 samples.

How the data were processed

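Per the labels, total RNA was taken from mouse embryonic stem (ES) cells of the lines AB2.2 and PL2F8 at days 0, 2, 4, 6 and 8 after LIF removal, extracted with QIAGEN RNeasy reagents, checked on an Agilent Bioanalyser and hybridized, labelled with biotin, to Illumina mouse bead arrays. Each line had 2 arrays at days 0, 2, 4 and 6 and 1 array at day 8, in all 18 arrays. The labels do not say whether the arrays of a line and day came from separate cultures, so every p-value below measures only the spread between these samples, which may be technical. Their number limits the precision, and the day 8 groups lent on the spread of the other groups because each held 1 array.

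The deposited probe table gave, per the file headers, an average signal (intensity), deposited as not normalized, and a detection p-value for each of 45281 probes on each array. In 445 of its lines (0.98%) the fields were shifted so that the values could not be assigned, and these probes were left out, which left 44836. The steps of the detection p-values were those of 936 negative controls. The table carried probe numbers without gene names, and the authors' series matrix carried gene names without probe numbers. Recomputing showed that the matrix held the quantile-normalized signal without background correction, averaged over probes of the same name. Probes were therefore named by matching their values to the matrix across the 18 arrays. Of its 30848 lines 30467 were reproduced, 21636 by 1 probe and 8831 by the mean of up to 14 neighbouring probes, and 381 were not. The largest distance of a match to 1 probe was 0.0132, while the next probe was always at least 0.0392 away, and 40 matches to a mean were ambiguous. The names were brought up to date with the platform annotation (13139), current gene symbols (5648) or older symbols (3212), and 8468 were kept as deposited. The gene symbols came from RefSeq for the mouse assembly GRCm38.

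The signal was corrected for background with the normal-exponential model of limma, with the mean and spread of the negative controls inferred from the detection p-values, an offset of 16 was added, and the arrays were quantile normalized on the log2 scale. A probe was kept when its detection p-value was below 0.05 on at least 2 of the 18 arrays, which kept 23879 probes, 23766 of them named. Each gene was represented by its probe with the highest mean signal, leaving 16076 genes, of which 5200 had more than 1 kept probe. Where a gene was not detected on any array of a comparison's lower side, its change was given as at least the fold reached from the lowest normalized signal of any detected probe on those arrays, or from the gene's own signal where that was higher (lowest signals between 4.68 and 6.89, median 4.75, on the log2 scale). Where a gene was undetected in only part of a side, such as 1 line, and in interactions, the model's value is given, which then rests in part on signal not above background.

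A linear model in limma had a mean for each line and day and 8 residual degrees of freedom, to which the moderated variance added 4.12 prior degrees of freedom. The spread of each gene was pooled over all groups. PL2F8 replicates at day 6 differed more (standard deviation of their difference 0.333) than those of the other groups (0.152 to 0.191). Standard errors that involve PL2F8 at day 6 may therefore be too small. PL2F8 at day 8 had no replicate to show its spread. Standard errors that involve it, as in the mean of the 5 daily differences between lines, may be too small as well. Changes over days were means of both lines with each line given the same weight, and the difference between lines was the mean of the 5 daily differences. The line by day interaction was tested at day 6 and, with a moderated F test, at any day. P-values were moderated t or F tests, adjusted by Benjamini and Hochberg within each comparison, and a gene was called below an adjusted p of 0.05. Intervals after ± are standard errors of the model unless stated otherwise.

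Before the data were examined, 30 gene lists were written from general knowledge of ES cells, with 653 entries, of which 625 had a probe. At least 5 measured genes were required, which left 29 lists with 526 genes. The list of Y-linked genes and Xist had 4 and was not tested. Lists were tested with camera against all other genes with the preset correlation of 0.01 and again with a correlation estimated from the residuals, and the p-values were adjusted over the lists. The genes to be named were fixed by rule at the same time. These were the 8 highest and 8 lowest called changes at day 6 with all 4 arrays on the same side of their line's day 0 mean, the 5 highest and 5 lowest at day 2, and the 3 highest and 3 lowest in each later interval and at day 8. The rule added the 10 highest and 10 lowest differences between lines with the same sign at all 5 days, the 10 genes with the smallest interaction p, the 4 genes with the smallest p of each list, and a set of 19 genes always reported. Provisional gene symbols were passed over in the ranks. Results of some named genes are not reported here. Of that set Sox1 and Pax6 were detected on 0 arrays and Xist on 1, so they were not tested. Among 140 named values with other kept probes of the same gene, 8 had another probe that passed the threshold in the opposite direction. These are given with the genes or here: Rbl1 at day 6 (-0.92 against 0.22), Hprt between lines (0.06 against -0.25, and -1.18 with median scaling) and Mybl2 between lines (1.30 against -0.26, and -0.094 with median scaling). For further named values another probe lay much nearer 0. At day 6 these included Apoa2 (4.52 against 0.60), Meg3 (2.84 against 0.23), Peg3 (2.07 against 0.24) and Fgfr2 (2.03 against 0.36). At day 2 they included Mapt (-3.62 against -0.17) and Esrrb (-1.36 against 0.01), and from day 2 to day 4 Adssl1 (2.56 against 0.05). Between lines they included Apoa2 (-3.78 against -0.58), Fgfr2 (-1.52 against -0.14), Actc1 (-1.795 against -0.275), Esrrb (1.10 against 0.05) and Mki67 (-1.24 against -0.33). For the day 6 interaction they included Mki67 (-1.55 against -0.48) and Fzd5 (-1.48 against -0.43).

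On simulated data with 200 changed genes among 16076, the day 6 comparison recovered 77.6% of genes changed by 0.5 on the log2 scale, 98.5% of those changed by 1 and 100% of those changed by 2, with 5.6% of the calls false. The day 6 interaction recovered 22.4%, 73.1% and 97.0%. The comparison of lines at day 0 recovered 41.8%, 92.5% and 100%. The share of false calls was 8.7% at day 4, 6.5% at day 8 and 6.6% between lines at day 0. Far fewer genes were changed here than were called in the data (67.9% at day 6), so recovery in the data may differ. In each of the 3 comparisons for which lists were tested on simulated data, 6 of 6 lists shifted by 0.5 were recovered and 0 unchanged lists were called. The noise was simulated independently for each gene, with the same spread on all arrays and without repeating the normalization. These rates therefore do not cover lists whose genes vary together, where more false calls are possible.

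The arrays were also analysed without background correction, with median scaling in place of quantile normalization, with the series matrix values, with other filters and offsets, with probes averaged, with array weights, with a block for replicate number, with an additive model and without each array in turn. Median scaling left the median of all genes away from 0 by -0.37 at day 6, -0.89 at day 8, 0.17 at day 6 in AB2.2, -1.08 at day 6 in PL2F8, -0.69 between lines and -1.42 for the day 6 interaction. The analysis without the 3 dim PL2F8 arrays of days 6 and 8 and the analysis restricted to genes detected on all arrays of days 0 and 6 were added after the data had been seen. The versions were R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.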

Results

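The arrays measured the transcripts of mouse embryonic stem (ES) cells of the lines AB2.2 and PL2F8 at days 0, 2, 4, 6 and 8 after LIF removal. LIF is the cytokine that keeps mouse ES cells undifferentiated through STAT3, so the series follows cells leaving that state, and each comparison asked which genes differed between days or between lines. Each line had 2 arrays at each of days 0, 2, 4 and 6 and 1 array at day 8. The mean signal of all AB2.2 arrays and of the PL2F8 arrays of days 0 to 4 lay between 283.6 and 492.7, with 41.9% to 45.0% of probes detected. The lowest of these were the PL2F8 arrays of day 4, with 283.6 and 286.0. The PL2F8 arrays of day 6 were dimmer, with mean signals of 137.4 and 134.8 and 40.0% and 37.8% of probes detected, and the PL2F8 array of day 8 had a mean signal of 60.1 with 20.9% detected. Replicate arrays correlated across genes at 0.996 to 0.998, except at 0.989 for PL2F8 at day 6. Genes are not independent replicates, so these correlations describe the arrays only.

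**Figure D1:**
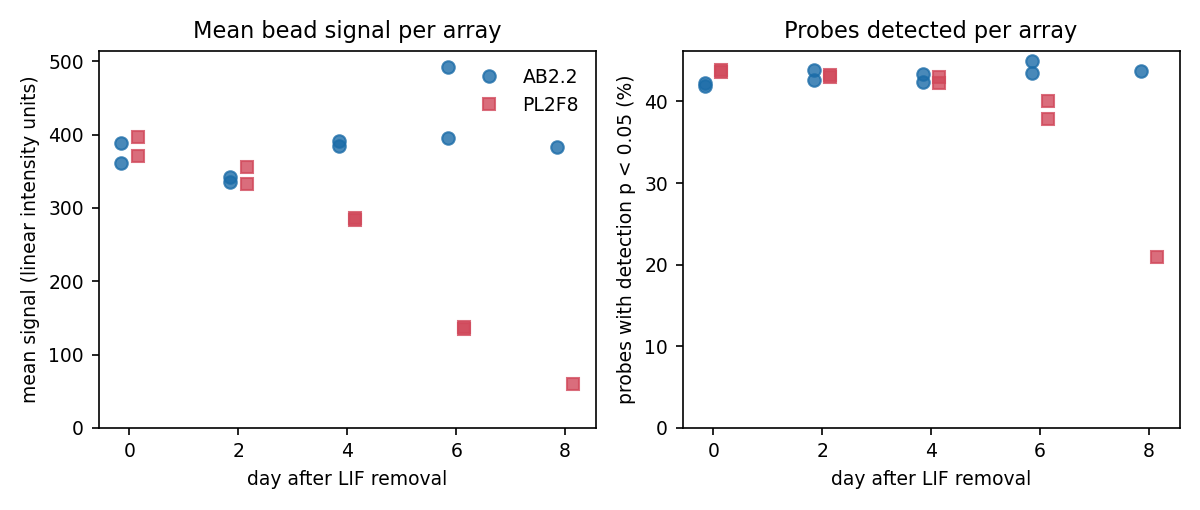
Mean signal and percentage of detected probes of each array by day and line. The PL2F8 arrays of days 6 and 8 were the dimmest.

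The first comparison asked what had changed at day 2 in both lines (4 arrays against 4). Among the genes with the largest rises were Fgf5, a marker of the early postimplantation epiblast (at least 15.6-fold, because it was not detected at day 0), and Ttr, which encodes transthyretin (at least 8.8-fold). Enpp2, which encodes autotaxin, rose by a log2 change of 3.47 ± 0.10. The rises of Lefty1, a Nodal antagonist, and Vrtn were 3.41 ± 0.06 and 3.21 ± 0.10. Fos and Egr1, immediate early transcription factors, fell by 4.79 ± 0.07 and 4.45 ± 0.06. Socs3, the feedback inhibitor of LIF and STAT3 signalling, fell by 4.19 ± 0.07, smooth muscle actin Acta2 by 3.73 ± 0.07 and the microtubule protein Mapt by 3.62 ± 0.08. The pluripotency genes Klf4, Esrrb, Zfp42 and Nanog fell by 2.59 ± 0.09, 1.36, 1.25 and 1.01 ± 0.07, where another Nanog probe gave -1.67. Sox2 fell by 0.37 and Pou5f1 was close to its day 0 level (-0.09, adjusted p = 0.38). The de novo DNA methyltransferase Dnmt3b rose by 2.22 ± 0.06. Krt8, Gata6 and Sox17 fell by 1.47, 0.82 and 0.60, Hprt rose by 1.79, and T did not pass the threshold (adjusted p = 0.056). Of 16076 genes 3571 were higher and 3744 lower (2443 and 5308 with median scaling), 379 and 322 of them by at least 2-fold.

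Grouped by list, the day 2 changes were a loss of naive pluripotency and of LIF targets and a gain of epiblast genes. Of 24 naive pluripotency genes 19 fell and 2 rose (median log2 change -0.92, adjusted p = 2.4e-09). Of 17 LIF and STAT3 targets 13 fell and 2 rose (-1.05, adjusted p = 1.8e-08), and of 14 genes of the primed epiblast 11 rose and 1 fell (1.80, adjusted p = 1.3e-08). Cholesterol synthesis genes rose (16 higher, 0 lower of 20, median 0.54, adjusted p = 1.3e-07). Mesenchymal and cytoskeletal genes fell (1 higher, 20 lower of 24, median -0.95, or -0.90 with undetected genes at their bounds, adjusted p = 2.3e-10), as did trophectoderm genes (1 higher, 12 lower of 14, median -0.64, or -0.57 at bounds). Germ cell genes (0 higher, 10 lower of 16, median -0.46), ATF4 stress genes (2 higher, 12 lower of 21, -0.36) and 2-cell-like genes (0 higher, 6 lower of 8, -0.40, or -0.32 at bounds) were lower too. Feeder fibroblast genes were lower (2 higher, 12 lower of 15, median -0.55, or -0.34 at bounds, adjusted p = 0.071 with an estimated correlation). Epithelial junction genes were higher (9 higher, 0 lower of 16, median 0.22, adjusted p = 0.18 with an estimated correlation), and so were interferon and antigen presentation genes (10 higher, 4 lower of 18, median 0.44, adjusted p = 0.14 with an estimated correlation). Hox cluster genes were lower (0 higher, 7 lower of 15, median -0.20, or -0.16 at bounds, adjusted p = 0.071 with an estimated correlation). Ectoderm and neural genes were slightly lower (0 higher, 5 lower of 12, median -0.04, adjusted p = 0.083 with an estimated correlation). With median scaling the Hox list was not called (adjusted p = 0.162). Adjusted over the list alone, the counts were 1 and 21 for mesenchymal genes, 3 and 13 for LIF targets, 1 and 10 for germ cell genes, 3 and 13 for ATF4 genes, and the same for the other called lists. In all 14 of 29 lists were called, 4 higher and 10 lower. Where the median and the mean of an uncalled list differed in sign, as for primitive streak (-0.04 and 0.31), imprinted genes (0.04 and -0.05) and p53 targets (-0.01 and 0.01), no direction is given.

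The main comparison asked what had changed by day 6 in both lines (4 arrays against 4). The largest rises were in genes of the visceral endoderm, which makes serum proteins: Ttr rose at least 55.4-fold and Apoa1, an apolipoprotein, by 5.76 ± 0.07. They were followed by the myosin light chain gene Myl3 (4.74 ± 0.10), the stress-induced gene Gadd45b (4.61 ± 0.07), and Apoa2 (4.52 ± 0.16). Next came carbonic anhydrase 4 Car4 (4.09 ± 0.07), the serine protease gene Tmprss2 (at least 13.7-fold) and alpha-fetoprotein Afp, not detected at day 0. The largest falls were in the transcription factors Gbx2 (-5.13 ± 0.07) and Egr1 (-4.47 ± 0.06). Next came Enox1 (-3.71 ± 0.09), the myosin gene Myo1f (-3.52 ± 0.10), the 18S ribosomal RNA probe Rn18s (-3.49 ± 0.15) and Cobl (-3.45 ± 0.09, where another probe gave 0.98). The keratin gene Krt42 (-3.44 ± 0.08) and the oocyte and early embryo gene Khdc3 (-3.37 ± 0.08) fell as well. In total 5463 genes were higher and 5455 lower (2663 and 9234 with median scaling), 1225 and 942 of them by at least 2-fold.

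Pluripotency genes were lower at day 6. Of 24 naive genes 23 fell and 1 rose (median log2 change -1.78, adjusted p = 4.3e-11), the smallest p-values being those of Jam2 (-2.72 ± 0.05), Zfp42 (-3.15 ± 0.08), Gdf3 (-2.30 ± 0.06) and Dnmt3l (-1.86 ± 0.05). Of 13 core pluripotency genes 12 fell and 1 rose (-1.09, adjusted p = 2.2e-05), among them Tdgf1 (-2.85 ± 0.06), Dppa2 (-2.98 ± 0.08) and L1td1 (-2.48 ± 0.07). Pou5f1 fell by 1.53 ± 0.08, Nanog by 1.12 ± 0.07, Sox2 by 1.06, Klf4 by 3.29 and Esrrb by 2.09, where another Esrrb probe gave 0.34. Another Nanog probe gave -2.65, so the size of its fall depends on the probe. LIF and STAT3 targets were lower (2 higher, 9 lower of 17, median -0.22, adjusted p = 0.057 with an estimated correlation). Gbx2, Egr1 and Socs3 (-3.02 ± 0.07) fell while Ier3 rose by 1.75 ± 0.05. Germ cell genes were lower (3 higher, 10 lower of 16, median -0.50, adjusted p = 0.057 with an estimated correlation), with Tex11 at -1.95 ± 0.06, Tuba3a at -1.37, Stk31 at -1.93 and Piwil2 at -1.39.

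Genes of several lineages rose by day 6. Of 29 primitive and visceral endoderm genes 25 rose and 2 fell (median log2 change 1.23, adjusted p = 2.0e-08), including Apoa1, Ttr, the cubilin partner Amn (2.90 ± 0.06) and Apoe (2.23 ± 0.05). Gata6 and Sox17, endoderm transcription factors, rose by 1.01 ± 0.06 and 1.04 ± 0.14. Trophectoderm genes rose (9 higher, 1 lower of 14, median 0.86, or 0.79 at bounds, adjusted p = 0.0023), with the keratins Krt18 (2.91 ± 0.06), Krt8 (2.33 ± 0.06) and Krt19 (1.99 ± 0.06) and the receptor Fgfr2 (2.03 ± 0.06). The list median was 1.46 in AB2.2 and 0.31 in PL2F8 (-0.48 with median scaling). Cdx2 was at least 2.5-fold higher on the mean of both lines, but at day 6 it was detected in AB2.2 only, where it was at least 5.9-fold higher. Epithelial junction genes rose (12 higher, 1 lower of 16, median 0.68, adjusted p = 0.12 with an estimated correlation), with Cldn3 at 2.35 ± 0.07, Esrp1 at 2.18 ± 0.06, Cldn4 at 1.90 ± 0.09 and St14 at 0.98. Epiblast genes were higher than at day 0 (12 higher, 1 lower of 14, median 0.87, adjusted p = 0.0009), with a median of 1.28 in AB2.2 and 0.32 in PL2F8 (-0.26 with median scaling), against 1.63 and 1.99 at day 2. The ETS factor Etv4 fell by 3.08 ± 0.06, Cldn6 and Sox11 rose by 2.88 ± 0.06 and 1.86 ± 0.06. Fgf5 was at least 3.7-fold higher on the mean of both lines, but at day 6 it was detected in AB2.2 only, where it was at least 13.8-fold higher. Dnmt3b did not pass the threshold on the mean of both lines (0.00, adjusted p = 0.96, or -1.03 with median scaling), with a change of 0.74 ± 0.08 in AB2.2 and -0.73 ± 0.08 in PL2F8. Primitive streak and mesendoderm genes rose (13 higher, 4 lower of 19, median 0.57, or 0.55 at bounds, adjusted p = 0.057 with an estimated correlation), with a median of 1.13 in AB2.2 and 0.11 in PL2F8 (-0.04 with median scaling). Without background correction this list was not called (adjusted p = 0.0528). Fgf17 fell by 2.23 ± 0.06, Lhx1 and Fgf8 were at least 3.2-fold and 5.6-fold higher and T, the mesoderm factor Brachyury, rose by 1.47 ± 0.07. Imprinted genes rose (13 higher, 3 lower of 23, median 0.32, or -0.07 with median scaling, adjusted p = 0.057 with an estimated correlation), with the noncoding RNAs H19 (2.87 ± 0.06) and Meg3 (2.84 ± 0.06), and with Dlk1 (2.04 ± 0.05) and Peg3 (2.07 ± 0.06).

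**Figure D2:**
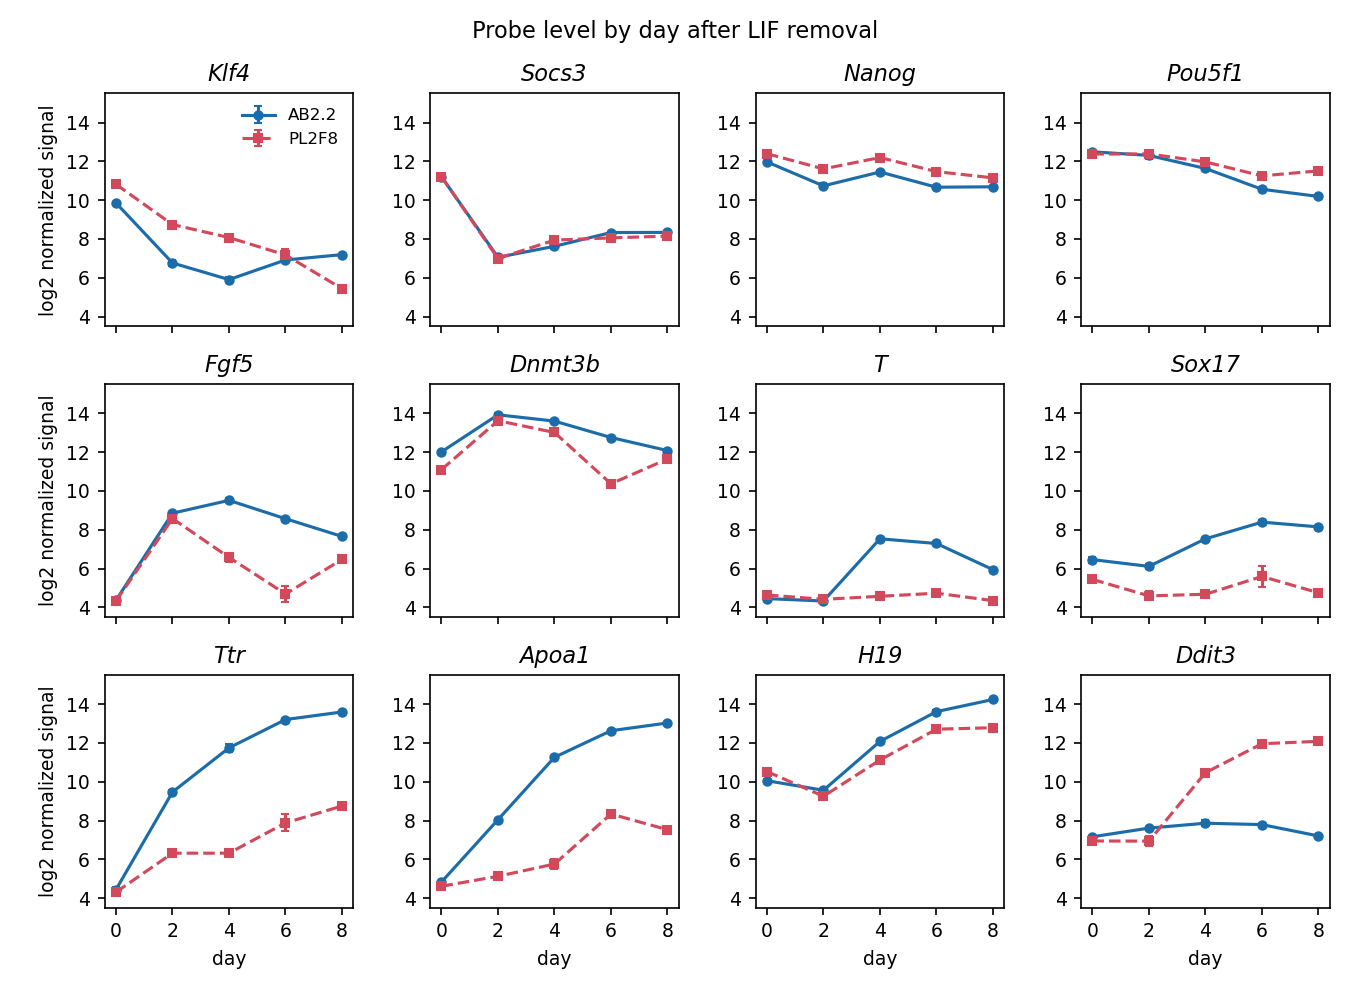
Normalized log2 signal of 12 genes by day in each line, as the mean and standard deviation of 2 arrays, or 1 array at day 8. The genes shown were chosen after the values had been seen.

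Proliferation and metabolism genes shifted by day 6. DNA replication genes fell (0 higher, 20 lower of 22, median log2 change -0.54, adjusted p = 2.2e-06), with Tyms at -1.88 ± 0.06, Gins1 at -1.30 ± 0.07, Ccne1 at -1.54 ± 0.09 and Mcm5 at -0.85 ± 0.05. G2/M and mitosis genes fell (0 higher, 16 lower of 19, median -0.42, adjusted p = 0.00091), with Kif11 at -0.77, Kif2c at -0.51 and Ccnb1 at -0.69. MYC and ribosome biogenesis genes fell (1 higher, 12 lower of 16, median -0.59, adjusted p = 0.0009), with Bop1 at -1.49 ± 0.07, Rrp12 at -1.18, Nop56 at -0.70 and Pes1 at -1.23, where Pes1 was 0.10 and not called in AB2.2 alone without the dim arrays. Oxidative phosphorylation genes fell (0 higher, 17 lower of 21, median -0.38, adjusted p = 0.0009), with Atp5j at -0.77 ± 0.05, Cox5a at -0.74 ± 0.05, Idh3a at -0.70 and Ndufs4 at -0.56. Glycolysis and hypoxia genes rose (15 higher, 4 lower of 23, median 0.40, adjusted p = 0.057 with an estimated correlation), with Ndrg1 at 2.06 ± 0.06, Vegfa at 1.56 ± 0.05 and Gpi1 at 1.40 ± 0.05, while Pfkp fell by 2.22 ± 0.06. Targets of p53 rose (13 higher, 0 lower of 18, median 0.43, adjusted p = 0.0009), with Bbc3 at 1.43 ± 0.05, Mdm2 at 0.99 ± 0.05 and Cdkn1a at 1.16 ± 0.06. Without the 3 dim PL2F8 arrays the day 6 comparison is AB2.2 alone (2 arrays against 2), and there neither the p53 list (adjusted p = 0.211) nor the G2/M list (adjusted p = 0.32) was called. With median scaling p53 targets (median -0.16, adjusted p = 0.377) and glycolysis (median -0.17, adjusted p = 0.348) were not called. Adjusted over the list alone, the counts were 1 and 16 for G2/M, 16 and 4 for glycolysis and the same for the other lists called at day 6. In all 16 of 29 lists were called, 8 higher and 8 lower.

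The other 13 lists did not pass at day 6, although single genes in them moved. Among mesoderm genes (10 higher, 4 lower of 18, adjusted p = 0.074) Actc1, cardiac actin, was at least 4.1-fold higher, Bmp4 fell by 1.39, and Msx1 and Flt1 rose by 1.65 and 1.36. Among ectoderm and neural genes (4 higher, 6 lower of 12, adjusted p = 0.31) Stmn2, Mapt and Ncam1 fell by 2.57, 2.47 and 1.06 and Nes rose by 2.04. Among mesenchymal genes (13 higher, 6 lower of 24, 14 and 6 adjusted over the list alone, adjusted p = 0.12) S100a6, Zeb1 and Vim fell by 1.78, 1.60 and 1.56 and Tpm1 rose by 1.36. Feeder fibroblast genes gave 7 higher and 6 lower of 15 (adjusted p = 0.56), with Timp1 at -2.10, Fbln1 at 1.67, Col6a1 at 1.39 and Mmp2 at 0.83, where Mmp2 became -0.01 with median scaling. ATF4 stress genes gave 6 higher and 11 lower of 21 (adjusted p = 0.29), with Ddit4 at 2.43 ± 0.07 and Ddit3 at 2.82 ± 0.09 against Chac1 at -2.07 ± 0.07 and Slc7a3 at -1.80 ± 0.06. Wnt, Nodal, FGF and BMP feedback genes gave 9 higher and 7 lower of 18 (10 and 7 adjusted over the list alone, adjusted p = 0.42), with Spry4 at -3.14 ± 0.08, Etv5 at -1.69 and Hey1 at 1.27. Chromatin and DNA methylation genes (4 higher, 11 lower of 22, adjusted p = 0.089) included Tet1, a DNA demethylase, at -1.75 ± 0.05, Chd1 at 1.46 and Phc1 at -1.07. Interferon genes (11 higher, 5 lower of 18, adjusted p = 0.15) included Psmb8 at 1.65 and B2m at 1.61 against Ifitm2 at -1.16 and Ifitm3 at -1.20. The remaining lists were 2-cell-like (1 higher, 5 lower of 8, adjusted p = 0.089), and D cyclins and CDK inhibitors (2 higher, 6 lower of 11, adjusted p = 0.35) and Hox clusters (7 higher, 2 lower of 15, adjusted p = 0.37). The last were cholesterol synthesis (5 higher, 9 lower of 20, adjusted p = 0.50) and heat shock and unfolded protein (7 higher, 8 lower of 21, adjusted p = 0.62). Fdps of the cholesterol list fell by 0.78 with its chosen probe and rose by 1.05 with another. The Y-linked genes Eif2s3y and Ddx3y were 0.98 and 0.86 higher, but in AB2.2 alone without the dim arrays Ddx3y was lower (-0.39, called). Zfy1 (0.12, which became -0.32 with median scaling) and Uty (0.09) did not pass the threshold.

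**Figure D3:**
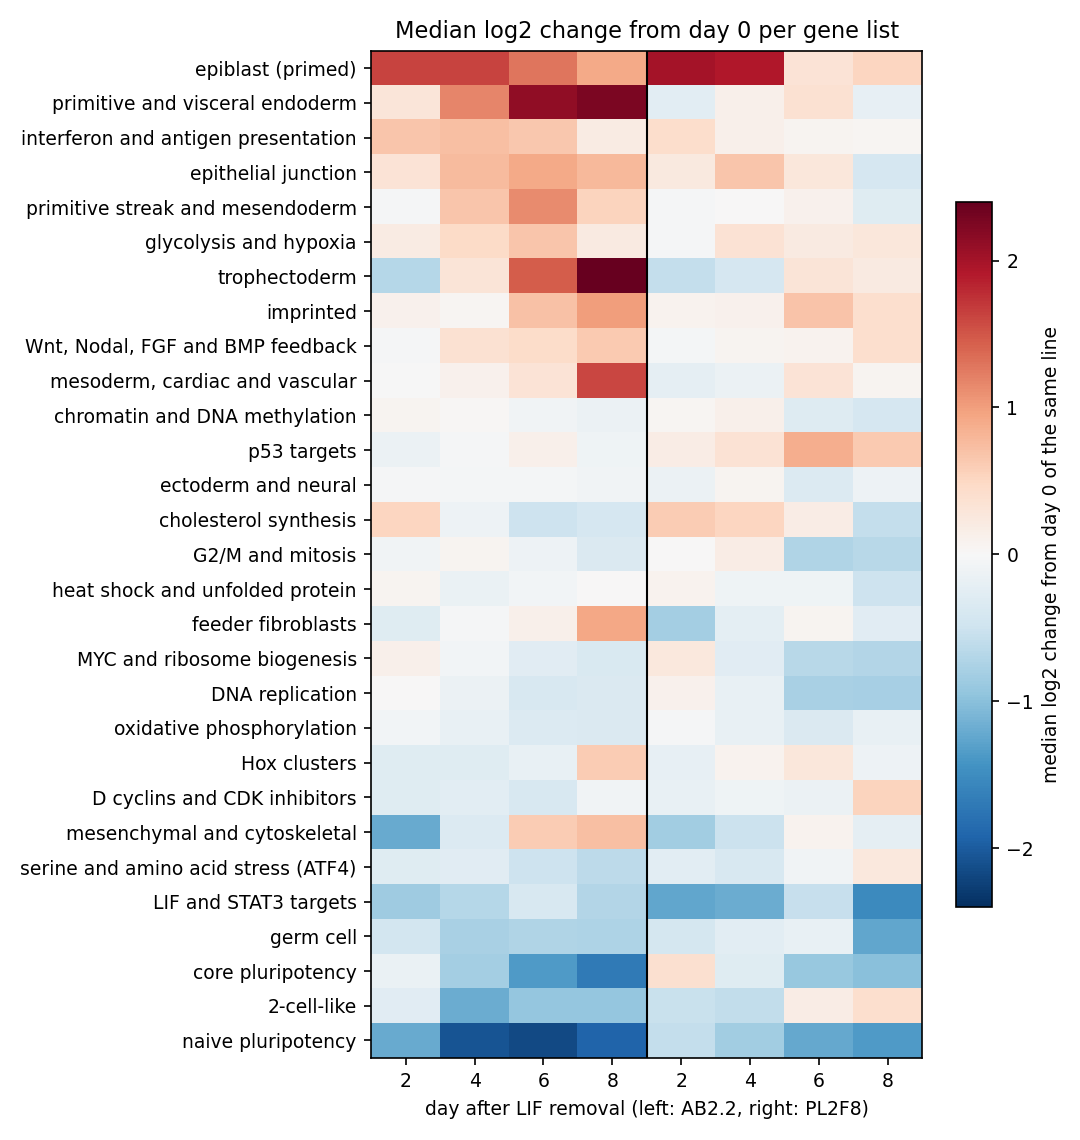
Median log2 change from day 0 of 29 gene lists at each day, with AB2.2 on the left and PL2F8 on the right. The median of the endoderm list at day 6 was 2.12 in AB2.2 and 0.37 in PL2F8 (-0.32 with median scaling).

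The days between and after asked when these changes came. From day 2 to day 4 the kinesin Kif1a, the neural progenitor filament Nes and the muscle enzyme gene Adssl1 rose most (2.72 ± 0.09, 2.65 ± 0.13 and 2.56 ± 0.07). Enox1, Gbx2 and Myo1f fell most (-2.95 ± 0.09, -2.58 ± 0.07 and -2.08 ± 0.10). From day 4 to day 6 Acta2, Dlk1 and the gut hormone Pyy rose most (2.88 ± 0.07, 2.45 ± 0.05 and 2.44 ± 0.06). Enpp2, Tdgf1 and Irgm2 fell most (-2.34 ± 0.10, -1.95 ± 0.06 and -1.89 ± 0.07). From day 6 to day 8, with 1 array per line at day 8, Igfbp5, the connexin Gja5 and Samd14 rose most (2.07 ± 0.06, 2.04 ± 0.13 and 1.98 ± 0.10). Snhg11, Pk3 and Vamp2 fell most (-3.00 ± 0.06, -2.60 ± 0.14 and -2.39 ± 0.10). These 3 were not detected on the dim PL2F8 array of day 8, so their values and ranks rest in part on signal not above background. Against day 0, day 8 was led by Ttr (at least 85.7-fold), Apoa1 (5.56 ± 0.09) and Myl3 (4.24 ± 0.12) and, among the falls, by Gbx2 (-5.27 ± 0.09), Zfp42 (-4.72 ± 0.09) and Klf4 (-4.02 ± 0.11). In PL2F8 these last 3 genes were not detected at day 8 either, and there they were at least 12.0-fold, 31.5-fold and 15.3-fold lower than at day 0. Dnmt3b was 1.75 ± 0.06 above day 0 at day 4 and T was 1.51 above. The counts were 5172 higher and 4528 lower at day 4 (4022 and 5943 with median scaling) and 5217 and 6023 at day 8 (1196 and 10699). From day 2 to day 4 they were 4459 and 3658, from day 4 to day 6 they were 3671 and 4174 (1132 and 9306). From day 6 to day 8 they were 4070 and 5297 (480 and 9432). The intervals from day 4 on had far fewer called genes without the dim arrays, then in AB2.2 alone, and with the additive model, as given below.

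The lines were then taken apart at day 6 (2 arrays against 2 in each). In AB2.2 the endoderm list rose by a median of 2.12 (27 higher, 0 lower of 29, 28 and 0 adjusted over the list alone, adjusted p = 1.7e-15). In PL2F8 it rose by 0.37 (14 higher, 3 lower of 29, adjusted p = 0.027, adjusted p = 0.17 with an estimated correlation), and with median scaling its median was -0.32 although the test stayed upward. Ttr rose at least 343-fold in AB2.2 and at least 8.9-fold in PL2F8, Afp at least 49.9-fold and at least 2.0-fold, and Apoa1 by 7.80 ± 0.10 in AB2.2 and at least 12.3-fold in PL2F8. T rose at least 5.7-fold in AB2.2, while in PL2F8 it was detected on 1 of 2 arrays at day 0 and on 0 of 2 at day 6, so no change is given there. Naive pluripotency genes fell in each line, by a median of 2.17 in AB2.2 (0 higher, 23 lower of 24, adjusted p = 1.7e-15) and 1.23 in PL2F8 (1 higher, 23 lower of 24, adjusted p = 6.7e-08). In AB2.2 4569 genes were higher and 4271 lower (6428 and 2774 with median scaling), and in PL2F8 5003 were higher and 5631 lower (1072 and 11235). Across genes the changes of the lines correlated at 0.742 at day 2, 0.664 at day 4, 0.462 at day 6 and 0.173 at day 8, and these genes are not independent replicates. Of the genes called in both lines, 95% had the same direction at day 2 and 76.9% at day 6.

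The interaction asked which changes differed between the lines. The genes with the smallest p at any day, with their day 6 values as PL2F8 minus AB2.2, were the sulfate transporter Slc13a4 (-5.77 ± 0.12), the stress-induced Nupr1 (4.62 ± 0.12), Apoa4 (-3.81 ± 0.10), and Gadd45g (5.14 ± 0.12). They were followed by the proliferation marker Mki67 (-1.55 ± 0.10), pepsinogen 5 Pga5 (-3.23 ± 0.10), Snorc (3.67 ± 0.13), the Wnt receptor Fzd5 (-1.48 ± 0.09), Dlk1 (-2.58 ± 0.10) and Flg (3.77 ± 0.12). Apoa4 was not detected at day 0 or in PL2F8 at any day, and Flg was detected only in PL2F8 at days 6 and 8, so these 2 values rest in part on signal not above background. At day 6 the endoderm list had 0 genes higher and 25 lower of 29 (0 and 26 adjusted over the list alone, median -1.78, adjusted p = 9.5e-11). Of 18 p53 targets 13 were higher and 0 lower (14 and 1, median 0.60, adjusted p = 0.00028), but with median scaling the median was -1.46 and the list was not called. Naive pluripotency genes had 17 higher and 3 lower of 24 (median 0.51, adjusted p = 0.0019), which with median scaling became -1.40 and was not called. G2/M genes had 0 higher and 13 lower of 19 (median -0.65, adjusted p = 0.0032). Genes past the interaction threshold numbered 12963 at any day and 8917 at day 6, with 4108 higher in PL2F8 and 4809 lower (601 and 11612 with median scaling). The dim PL2F8 arrays are in this comparison, and their effect on its size was not separable from the line.

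The last comparison asked how PL2F8 differed from AB2.2 on the mean of the 5 days (9 arrays against 9). Highest in PL2F8 were the placental hormone genes Prl2c2 (4.57 ± 0.04) and Prl2c3 (4.39 ± 0.04), whose near-identical sequences leave open which gene the probes read. They were followed by Brca1 (3.63 ± 0.07, where another probe gave -0.50), the X-linked homeobox gene Rhox13 (2.93 ± 0.04), and Aoc3 (2.67 ± 0.05). Then came Xlr5a (at least 5.2-fold), Xlr4a (2.55 ± 0.04), Efhc2 (2.55 ± 0.06) and Dmrtc1c1 (2.53 ± 0.05). The Xlr genes form a family of similar sequences, so their assignment is uncertain. Lowest were Apoa2 (-3.78 ± 0.11, where another probe gave -0.58), Ttr (-3.78 ± 0.08), Acta2 (-3.78 ± 0.05), Apoa1 (-3.69 ± 0.05), and Spink1 (-3.64 ± 0.05). Next were Clic6 (-3.37 ± 0.07), Lpar6 (-3.28 ± 0.05), Lgals2 (-3.15 ± 0.10) and the endocytic receptor genes Cubn (-3.14 ± 0.04) and Dab2 (-3.10 ± 0.04). In total 5461 genes were higher and 5992 lower (1072 and 11463 with median scaling), 350 and 522 of them by at least 2-fold.

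All 29 endoderm genes were lower in PL2F8 (median log2 difference -2.03, adjusted p = 2.1e-14), including Amn at -2.96, and Gata6, Sox17 and Afp were lower by 1.94, 2.32 and 2.69. Primitive streak genes were lower (0 higher, 14 lower of 19, median -0.71, adjusted p = 8.6e-05), with Lhx1 at -2.35, Sp5 at -2.10, T at -1.37 and Fgf8 at -1.59. Mesenchymal genes were lower (2 higher, 21 lower of 24, -0.66, adjusted p = 7.6e-06), with Tpm1 at -1.52, Myl9 at -1.69 and Ccn2 at -1.20. Epiblast genes were lower (0 higher, 9 lower of 14, -0.34, adjusted p = 0.0033), with Cldn6 at -1.59, Sox11 at -1.57, Dnmt3b at -0.93 and Fgf5 at -1.66. All 16 germ cell genes were higher in PL2F8 (median 0.99, adjusted p = 1.1e-07), among them Tuba3a (2.30 ± 0.05), Stra8, which starts meiosis (1.90 ± 0.04), Dazl (1.76 ± 0.05) and Tex13b (1.99 ± 0.06). Naive pluripotency genes were higher (19 higher, 2 lower of 24, 0.62, adjusted p = 7.6e-06) with Jam2 at 1.41. With median scaling the list was not called (median -0.38, adjusted p = 0.245) and Klf5 (1.11) and Tcl1 (1.16) became -0.27 and -0.15. Under that scaling the values of Pou5f1 (0.46), Nanog (0.66, where another probe gave -0.23), Sox2 (0.61) and Esrrb (1.10) also became negative (-0.89, -0.68, -0.48 and -0.25). Klf4 was 0.72 higher, and Socs3 (-0.04, adjusted p = 0.45) did not pass the threshold. Zfp42 (-0.00, adjusted p = 0.96) did not pass it either, but was 0.98 higher in PL2F8 without the day 8 arrays and 1.13 higher without the dim arrays, and called in both. Oxidative phosphorylation genes (15 higher, 1 lower of 21, 0.19, adjusted p = 0.0057) were higher, with Cox6c at 0.43, and lower with median scaling (median -1.02, Cox6c -0.79).

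The adjusted p of 7 more lists called between the lines was above 0.05 with an estimated correlation. Epithelial junction genes were lower (1 higher, 13 lower of 16, median -0.46, adjusted p = 0.13 with an estimated correlation), with Esrp2 at -1.61 and Lsr at -1.25. Imprinted genes were lower (4 higher, 14 lower of 23, -0.33, adjusted p = 0.097 with an estimated correlation), with Igf2 at -2.40 ± 0.04, Peg3 at -1.27 and Grb10 at -1.20. Impact of this list was higher at 0.87, and became -0.41 with median scaling. Trophectoderm genes were lower (2 higher, 10 lower of 14, -0.51, adjusted p = 0.07 with an estimated correlation), with Krt8 at -1.35, Fgfr2 at -1.52 and Cdx2 at least 1.7-fold lower. Mesoderm genes were lower (4 higher, 11 lower of 18, -0.46, adjusted p = 0.097 with an estimated correlation), with Flt1 at -2.29 and Actc1 at -1.80, and were not called with median scaling (adjusted p = 0.143). Myl4 of this list was higher in PL2F8, and became -0.18 with median scaling. The p53 targets (11 higher, 3 lower of 18, 0.22, adjusted p = 0.073 with an estimated correlation) included Sesn1 at 0.84 and Bbc3 at 0.70 (Bbc3 -0.12 without the dim arrays), which became -0.42 and -0.66 with median scaling, where the list turned lower without being called (adjusted p = 0.0649). G2/M genes (2 higher, 11 lower of 19, -0.16, adjusted p = 0.10 with an estimated correlation) included Mki67 at -1.24 (0.09 and not called without the dim arrays) and Aurkb at -0.55. MYC and ribosome biogenesis genes (1 higher, 10 lower of 16, -0.17, adjusted p = 0.097 with an estimated correlation) included Polr1b at -1.21 and Pes1 at -0.72 (0.10 and not called without the dim arrays). The MYC list was not called with the series matrix values or with probes averaged. It also lost its call without AB2.2 day 2 replicate 2, PL2F8 day 4 replicate 2 or PL2F8 day 6 replicate 1. The G2/M list was not called with probes averaged or without PL2F8 day 6 replicate 1. In all 14 of 29 lists were called, 4 higher and 10 lower (2 and 15 with median scaling), and the counts adjusted over the list alone were the same. Without the 3 dim PL2F8 arrays, over days 0, 2 and 4 of both lines, 6 of these lists were not called: mesoderm (adjusted p = 0.78), trophectoderm (0.703), imprinted (0.0503), p53 (0.722), G2/M (0.956) and MYC (0.21). Among uncalled lists the median and the mean or the test differed in sign for core pluripotency (-0.01 and 0.02), LIF targets (-0.03 and 0.18), glycolysis (-0.08 and 0.03) and cholesterol synthesis (-0.02 and 0.01).

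At day 0, before LIF was removed, the lines already differed (2 arrays against 2). Germ cell genes were higher in PL2F8 (12 higher, 0 lower of 16, 12 and 1 adjusted over the list alone, median log2 difference 0.89, adjusted p = 1.2e-07), with Stra8 at 2.66 ± 0.08 and Dazl at 1.85 ± 0.10. Endoderm genes were lower (0 higher, 14 lower of 29, -0.26, adjusted p = 4.8e-07), with Gata6 at -1.46 ± 0.08, Dab2 at -1.91 ± 0.09 and Amn at -1.72 ± 0.09. Mesenchymal genes were lower (3 higher, 12 lower of 24, -0.50, adjusted p = 0.00038), with Acta2 at -2.56 ± 0.10. Feeder fibroblast genes were higher (9 higher, 2 lower of 15, 0.49, adjusted p = 0.058 with an estimated correlation). Dppa3 (-2.98 ± 0.13), an early embryo and germ line gene, and Lefty1 (-3.31 ± 0.08) were lower, both chosen after the values had been seen. In total 2295 genes were higher and 2099 lower (3474 and 1139 with median scaling), 195 and 105 of them by at least 2-fold. Their total of 4394 was 2835 without PL2F8 day 0 replicate 2.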

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

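The tests by other splits of the arrays were chosen beforehand. The test of day 6 interaction signs between days 2 and 4 was written before its result was seen, but without the dim arrays, an analysis added after the data had been seen, and the other tests in this part were chosen only after the results had been seen. What drew attention to the results here is a tested difference between the lines in the same contrast, day against day 0.

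The response to LIF removal differed between AB2.2 and PL2F8: the interaction passed the threshold for 4799 genes at day 4, 8917 at day 6 and 12963 at any day, and 10 lists were called at day 4 and 11 at day 6 (7 and 8 with an estimated correlation). The dim PL2F8 arrays of days 6 and 8 are not in the day 4 contrast and reach it only through the shared normalization, filter and variance, and 5483 genes passed there in an analysis without them. In that analysis 6576 genes passed at any day, then over days 2 and 4 only. For the part at day 6, 79.4% of 8768 genes of the day 6 interaction had the same sign of interaction from day 2 to day 4 without the dim arrays, against 56.5% of 6973 other genes. Those signs argue against the dim arrays of days 6 and 8 alone, but not against a loss of signal in PL2F8 that had begun by day 4, where its arrays had mean signals of 283.6 and 286.0 against 370.6 and 396.1 at day 0. What stays open is such a loss, how far the dim arrays could have enlarged the day 6 and day 8 interactions, and whether the lines themselves or anything else that differed between their samples lay behind the rest, which was not tested.

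Primitive and visceral endoderm genes were higher in AB2.2, which dim PL2F8 arrays of days 6 and 8 do not account for, because without them 89.7% of the list (26 of 29 genes) passed the threshold and was lower in PL2F8 over days 0, 2 and 4, and 0 genes were higher. A larger share of differentiated cells of every kind in AB2.2 was tested with 4 other lineage lists. In PL2F8 minus AB2.2, 4 of 4 lay above the endoderm list by more than 2 standard errors. This cannot decide the question, because these lists had hardly risen by day 4 even in AB2.2 and could not be lowered alike. From day 0 to day 4 their AB2.2 medians were 0.1 (mesoderm), -0.05 (ectoderm and neural), 0.3 (trophectoderm) and -0.02 (feeder fibroblasts). The endoderm median was 1.17. In PL2F8 minus AB2.2 over days 0, 2 and 4, without the dim arrays, the endoderm list had a mean of -1.54 ± 0.17, against -0.10 ± 0.19 for mesoderm, 0.21 ± 0.23 for ectoderm and neural genes, -0.07 ± 0.17 for trophectoderm and 0.40 ± 0.15 for feeder fibroblasts. Here ± and the standard errors are taken over the genes of a list, which are not independent, and do not measure the spread between arrays. The primitive streak list (-0.71 ± 0.15, 13 lower and 0 higher) and the mesenchymal list (-0.60 ± 0.21, 17 lower and 3 higher) were lower in PL2F8 too. A larger share of differentiated cells in AB2.2 therefore stays open. What else lay behind the difference was not tested.

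Ddit3, Nupr1 and Gadd45g, genes induced by cell stress, were higher in PL2F8 relative to AB2.2 after LIF removal. Dim PL2F8 arrays of days 6 and 8 cannot be the whole cause, because 3 of 3 genes passed the day 4 interaction test without them (2.91 ± 0.19, 2.64 ± 0.12 and 4.09 ± 0.13). Nupr1 and Gadd45g had been picked by an interaction test that included day 4, so their day 4 result is not independent of that choice. At day 4 the tables also argue against a rise of the ATF4 target list as a whole in PL2F8, where 21.1% of the other list genes (4 of 19) were higher than at day 0 and 13 were lower. At day 6 this stays open relative to AB2.2, since the list was at -0.08 in PL2F8 and -0.49 in AB2.2 and its interaction had 10 higher and 5 lower of 21 genes (11 and 6 adjusted over the list alone, median 0.38, or -1.43 with median scaling, adjusted p = 0.023, adjusted p = 0.066 with an estimated correlation). The day 6 interactions of Nupr1 (4.62) and Gadd45g (5.14) might in part stem from the dim arrays, and whether a culture condition or the line led to the difference was not tested.

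The other genes with the smallest interaction p are given by their day 6 values. Slc13a4 (-5.77), Apoa4 (-3.81), Pga5 (-3.23) and Dlk1 (-2.58) rose less in PL2F8 or fell there, and each had a day 4 interaction of the same sign without the dim arrays (-4.52 ± 0.12, -3.27 ± 0.20, -4.07 ± 0.10 and -1.59 ± 0.11). Apoa4 was not detected at day 0 or in PL2F8, so its values rest in part on signal not above background, and at day 4 it was at least 6.1-fold lower in PL2F8 than in AB2.2. Snorc (3.67) rose in PL2F8 and fell in AB2.2, and its day 4 interaction without the dim arrays had the same sign (1.87 ± 0.14). Mki67 (-1.55) and Fzd5 (-1.48) had no interaction past the threshold at day 4 without those arrays (adjusted p = 0.83 and 0.36). Flg (3.77) was detected on the dim arrays only.

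Other splits of the same arrays were fitted to ask whether chance can be excluded for the counts. These fits used an additive model, for days on only the arrays of the days compared, and gave fewer genes than the main model. At day 2, for example, they gave 6339 against 7315. The statements below hold for the counts of these fits only. With each array taken as independent, which the labels do not show, the real split gave more genes than any other at day 2 (1 of 35 splits gave as many, the real one with 6339 genes and the highest other with 1019), day 4 (1 of 35, 7905 against 455), day 6 (1 of 35, 6387 against 550), from day 2 to day 4 (1 of 35, 5892 against 1111) and between lines (1 of 100, 4758 against 0). The real effect of day or line stayed in the residual of the other splits and could lower their counts. These shares alone therefore do not exclude chance. If replicate arrays are technical, only 3 splits of each comparison of days keep replicates together, too few for a share under 0.05, and the values above are the real and the highest other among those 3. The other splits between lines were drawn without keeping replicates together, so the same limit holds there. For the change from day 4 to day 6 chance cannot be excluded (2 of 35 splits, the real one with 2620). The split that parted these arrays by line gave 5224 genes, a structure of the samples. The number of called lists was not beyond that of other splits at day 2 (6 of 35 splits gave as many, 13 for the real split and 15 for the highest other), at day 6 (10 of 35, 15 against 18) or between lines (28 of 100, 9 against 14). Chance is therefore not excluded for these numbers. Effects of day or line remained in the data of the other splits, so this comparison cannot tell chance from such structure, for genes or for lists.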

How the results depend on the processing

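The alternatives without the dim arrays and with genes detected on all arrays of days 0 and 6 were chosen after the data had been seen, and all others before. Of 9424 alternative values of 295 named gene values, 9326 counted as the same, 36 were weaker, 22 stronger and 40 reversed. A change of sign counted as reversed only where the main or the alternative value was called, and otherwise as the same. Of 498 alternative counts 465 stayed within 1.5 times the main value. The cause was not tested for any changed result below unless stated. Signal over background limits the PL2F8 arrays of days 6 and 8 most. Models with the chip as a fixed or a random block were not run, because the sources used here do not give the chip.

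With an absolute log2 change of at least 1 required, which by construction lowers counts, the genes called were 701 at day 2, 1445 at day 4, 2167 at day 6 and 3364 at day 8. They were 587 from day 2 to 4, 328 from day 4 to 6 and 1812 from day 6 to 8, 2238 at day 6 in AB2.2, 3507 at day 6 in PL2F8, 872 between lines and 300 between lines at day 0. The interaction had 3325 at day 6 and 7940 at any day. The additive model, which puts the interaction in the residual, gave 1811, 4172, 5912 and 5870 at days 2, 4, 6 and 8. It gave 2082, 941 and 1707 for the intervals and 4758 between lines. Its effect of day 6 is shared by both lines, so it gives no count for PL2F8 or AB2.2 alone. Without the dim arrays, 4164 genes were called from day 4 to 6 and 3052 from day 6 to 8, both then in AB2.2 alone, and 6576 for the interaction at any day, then over days 2 and 4. With an estimated inter-gene correlation 9, 10 and 7 lists were called at day 2, day 6 and between lines, and with fry, which tests against no change instead of other genes, 26, 28 and 27.

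With the replicate block 7179, 9574, 10838 and 10916 genes were called at days 2, 4, 6 and 8, and 7958, 7735 and 9031 in the intervals. There were 8727 and 10556 at day 6 in AB2.2 and PL2F8, 11269 between lines, and 4131 between lines at day 0. The interaction gave 8779 at day 6 and 12707 at any day, and 14, 16 and 15 lists were called. The replicate numbers did not pair the arrays: the differences between replicates correlated between groups at -0.026 to 0.043.

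Without each array in turn, the counts ranged over 6493 to 8009 at day 2, 8956 to 10263 at day 4, 10287 to 11178 at day 6, and 10739 to 11714 at day 8. They ranged over 7571 to 9470 at day 6 in AB2.2, 9536 to 10634 at day 6 in PL2F8, 9585 to 11843 between lines and 2835 to 5137 between lines at day 0. For the interaction they ranged over 7969 to 9277 at day 6 and 10057 to 13528 at any day. The lowest count at day 0 came without PL2F8 day 0 replicate 2. Between lines, the mesoderm, trophectoderm, imprinted and p53 lists were not called without either of the day 8 arrays. At day 2 the ectoderm and neural list was not called without AB2.2 day 2 replicate 2. Lists ranged over 13 to 14, 16 to 17 and 12 to 16.

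Median scaling reversed, at day 6, Mmp2 (-0.009), Hsp90b1 (-0.15), Herpud1 (-0.21), Kdm3a (-0.13), Zfy1 (-0.32) and Dnmt3b (-1.03). Between lines it reversed Pou5f1 (-0.89), Nanog (-0.68), Sox2 (-0.48), Esrrb (-0.25), Hprt (-1.18), Mybl2 (-0.094), Klf5 (-0.27), Tcl1 (-0.15), Myl4 (-0.18), Impact (-0.41), Sesn1 (-0.42), Bbc3 (-0.66), Mdm2 (-0.66), Plk2 (-0.67), Cox7a2 (-0.90), Cox6c (-0.79) and Uqcrc1 (-1.02). This scaling leaves the dim arrays with a narrower spread of values. Fdps at day 6 became 0.14 with probes averaged. Zfp42 between lines, near 0 in the main analysis, became 0.13 without background correction, 0.16 with an offset of 50, 0.13 with the series matrix values, 0.984 without either or both day 8 arrays and 1.13 without the dim arrays. Without each other array in turn its lowest value was -0.04. Without the dim arrays, at day 6, Hoxd4 (-0.13), Hoxb7 (-0.23), Tcstv1 (-0.59), Pes1 (0.10), Ddx3y (-0.39) and Zfy1 (-0.66) reversed, and between lines Bbc3 (-0.12), Mki67 (0.088) and Pes1 (0.10).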

Other observations

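The genes of this part were chosen after their values had been seen, and no test was added. The Y-linked genes Eif2s3y and Ddx3y were detected on all 18 arrays, so transcripts of a Y chromosome were present in both lines, and Xist, the RNA that coats an inactive X chromosome, was detected on 1 array. H19 rose at day 6 by 3.56 ± 0.08 in AB2.2 and 2.18 ± 0.08 in PL2F8, and Igf2, its neighbour in the same imprinted domain, by 2.91 ± 0.09 and 0.72 ± 0.09, the value of Igf2 in PL2F8 becoming -1.30 with median scaling (2 arrays against 2 in each line). The epiblast factor Pou3f1 rose by 3.15 ± 0.08 at day 2 in both lines together, and the immunoproteasome gene Psmb8 by 2.50 ± 0.06.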
